A study of Caenorhabditis elegans with 3 samples.

How the data were processed

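Binding of CEH-14, a LIM homeodomain transcription factor, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in Caenorhabditis elegans at the L2 larval stage. The strain, OP73, expresses CEH-14 fused to GFP and a FLAG tag, and an anti-GFP antibody was used. Per the labels' protocols, worms were grown in liquid culture with E. coli as food at 20 °C and cross-linked in 2% formaldehyde for 30 min. Chromatin was then sheared to fragments of 200 to 800 bp. The series holds 3 libraries, 2 of them ChIP libraries (replicates 1 and 2) and 1 an input library of chromatin without immunoprecipitation, taken from replicate 2. Per the series' design text, both ChIP libraries are biological replicates, and replicate 1 was at a later L2 stage, so replicate and stage cannot be separated.

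Both kinds of deposited file were used. Each ChIP library had a peak list with 1 q-value (adjusted p-value) per region, which the authors had called with PeakSeq for each replicate on its own, per the file headers and the source column. Coordinates are 1-based on WormBase WS180, per the file headers, and every deposited q-value lay at or below 0.01. The q-values are the authors' own and were used only to rank peaks within a list and to work out the scaling they imply. Each of the 3 libraries also had a read file in which the authors' aligner gave every 30-base read a match class, the counts of genome positions matched with 0, 1 and 2 differences and, for a read placed once, its position. The layout is that of ELAND, per the file itself. The settings of both programs are not given in the sources used here, and the read files do not name their genome build, which was taken to be that of the peak lists.

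Reads placed once were counted after moving each from its 5' end by 100 bp towards the fragment centre. ChIP replicate 1 had 1779579 such reads of 4044633, ChIP replicate 2 had 2589795 of 4491161 and the input had 1124270 of 2641457. Peaks were called shared when they overlapped by at least 1 bp, and the chance level came from 1000 circular rotations of the replicate 1 peaks within each chromosome (one-sided). Overlapping peaks of both lists were merged into regions. Enrichment was the ratio of RPM (reads placed once, scaled to the library's total of such reads), ChIP over input, with the input set to at least 3 reads. Intervals of ratios are exact conditional binomial 95% intervals and those of shares are exact Clopper-Pearson intervals. Reads carry no molecular identifiers, so intervals and floors cover counting error only. The exception is the interval of the median ratio between replicates, which comes from the ranked ratios of the regions. The correlation between replicates used log2 of RPM plus a pseudocount of 1, without dividing by the shared input.

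Counts in 500-bp windows with a mean of at least 5 reads were compared between ChIP and input with edgeR's quasi-likelihood test (version 4.0.16, R 4.3.3), scaled by TMM factors from 10000-bp bins, with Benjamini-Hochberg adjustment at 0.05. This fit has 1 residual degree of freedom before moderation, and the single input is assumed to vary as the ChIP libraries do. The median prior degrees of freedom were infinite, so variances were shared across windows and not estimated for each one. DESeq2 (version 1.42.0) was an alternative. On simulated data with 200 changed windows among 163187 tested, the edgeR fit found 0% of the windows raised 2-fold and 13% of those raised 4-fold, with 3 false calls. Because both replicates were compared with the same input, 100 pairs of unchanged ChIP libraries were simulated against it. On simulated data with 200 windows raised 4-fold, the calls in both replicates found 69.5% of them among 169337 windows, along with 65 windows that had not been raised.

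No genome sequence was given, so sequence around peaks was rebuilt from the libraries' own placed reads by the majority base. These covered 70.1% of the positions. At positions read more than once, 99.3% of read bases matched the majority, and bases read once could not be checked. Bases were missing at 1.26% of positions in centres of shared regions and 12.4% in flanks. Words were searched on both strands within 100 bp of the region midpoint and in both flanking stretches of the same width 500 bp away, with bases missing in one stretch masked in the other. Exact two-sided McNemar tests compared the centre with each flank, and the larger p of the pair is given. A further control used stretches more than 2000 bp from any peak, matched on GC content to the read summit. The word test was checked on simulated data with a planted word, which it found. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used for all other steps.

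The gene table at hand belongs to WBcel235, another build than WS180, and no coordinates were converted. The share of peaks at promoters, the 25 gene lists, the RNA gene classes and the depth at ceh-14 and unc-119 were therefore not analysed here, although they had been planned before the data were examined. The rule for what to name, fixed at the same time, was applied to regions by position. It takes the 15 shared regions with the largest value of the smaller of the replicates' ratios over input, and the 5 regions at each end of the ratio of replicate 1 over replicate 2 among those with at least 20 reads. Alternatives covered the overlap and the strength of peaks, the scaling, repeated reads, the read shift, the pseudocount, the stretch width and, chosen after the data were seen, leaving out chromosome I, the read summit as centre, the length of regions and GC-matched stretches.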

Results

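The series asked where CEH-14 binds in L2 larvae. CEH-14 belongs to the LIM homeodomain family, whose members are known to act in the specification of neurons. It was measured in 2 ChIP libraries and 1 input library of strain OP73. Of the reads, 44.0% were placed once in ChIP replicate 1, 57.7% in ChIP replicate 2 and 42.6% in the input. Unmatched reads made up 49.5%, 33.5% and 50.0%. Further copies of a read at the same position and strand were 7.71% of placed reads in ChIP replicate 1, 7.72% in ChIP replicate 2 and 1.90% in the input. Mitochondrial reads were 0.164% and 0.138% of placed reads in the ChIP libraries and 0.965% in the input.

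The first comparison was between the peak lists of the replicates. The authors' list held 1495 peaks for replicate 1, with a median width of 313 bp, and 2303 for replicate 2, with a median width of 195 bp. In each list 676 peaks overlapped a peak of the other, which is 45.2% of replicate 1 and 29.4% of replicate 2. Rotated positions gave a mean of 2.17% and at most 3.61% of replicate 1 (one-sided permutation p = 0.000999, the smallest that 1000 rotations can give). The series' design text gives a concordance just over 50% at a p-value of 0.05, a looser threshold than the q-value of 0.01 in the deposited lists. Sharing depended on the rank of a peak. With each list divided into 4 equal parts by q-value, it was 77.7% in the part of replicate 1 with the smallest q-values and then 48.7%, 30.5% and 24.1%. In replicate 2 the parts gave 64.3%, 25.7%, 15.5% and 11.98%.

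Both lists used the same input, which by itself makes calls coincide. Among 169337 windows of 500 bp, 1423 lay above the scaled input at p = 0.001 or less in replicate 1 and 2362 in replicate 2, by a binomial test of reads that compares libraries and not conditions. Both replicates had 589 of these windows. Simulated unchanged libraries gave a mean of 63.5 windows in both and at most 83, from means of 192 and 645 calls. There 33.1% of the shorter list coincided. The observed share was 41.4%, but of longer lists, so these shares are not like for like. Independent lists of the observed lengths would share 19.8 windows. The input is a single library and cannot be divided, so part of the sharing may come from it.

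Peaks were spread unevenly over the chromosomes. Chromosome I held 678 of the 1495 peaks of replicate 1 (45.4%) and 862 of the 2303 peaks of replicate 2 (37.4%), though it gave 15.9% of the input reads. This is 44.98 and 57.19 peaks per Mb, against 7.90 to 14.7 and 14.5 to 20.6 on the other chromosomes. The median factor on the input counts implied by the authors' q-values was 0.921 on chromosome I and 1.92 elsewhere in replicate 1, and 1.24 and 2.39 in replicate 2. It is an estimate from recounted reads, with each p-value taken from the q-value and its rank in the list. Only peaks with at least 8 input reads were used, 285 and 270 of those on I in replicates 1 and 2. Peaks on chromosome I had lower ratios than the others. Their median ratio over input was 2.11 in replicate 1, against 2.74 elsewhere, and 1.57 in replicate 2, against 1.98. Of the 1495 and 2303 peaks merged into 3111 regions, 665 regions held peaks of both replicates, 323 on chromosome I and 342 on the other chromosomes. Without chromosome I, 42.1% of the replicate 1 peaks were shared. Within chromosomes II to X the shared regions had no preference for the middle of a chromosome. With each chromosome divided into 3 equal parts, the middle part held 116 of 342 (33.9%, 95% interval 28.9 to 39.2%) against 35.2% of the input reads (exact binomial p = 0.651, two-sided).

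**Figure D1:**
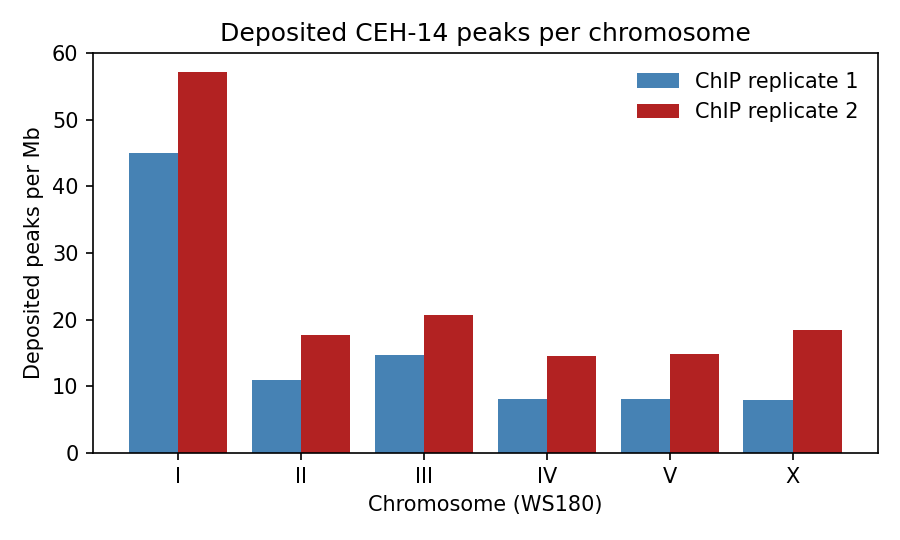
Deposited peaks per Mb of each chromosome (WS180) in the lists of ChIP replicates 1 and 2. Chromosome I has 44.98 and 57.19 peaks per Mb, and no other chromosome has more than 14.7 and 20.6.

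The second comparison was of the ChIP libraries with the input at these regions. Shared regions had a median of 2.53 times the input in replicate 1 (quartiles 2.00 and 3.43) and 2.04 times in replicate 2 (quartiles 1.61 and 2.75), with a median of 11 input reads. No test was made, because peaks were chosen for enrichment in these same libraries. On chromosomes II to X the medians were 2.98 and 2.37, and on chromosome I they were 2.18 and 1.74. Shared regions covered 0.430% of the genome. They took 2.15% of the reads of ChIP replicate 1, 1.74% of ChIP replicate 2 and 0.921% of the input. On chromosomes II to X, depth within 250 bp of the region midpoint was 3.43 times that 2 to 3 kb away in replicate 1 (95% interval 3.36 to 3.51) and 2.94 times in replicate 2 (2.89 to 3.00). The input was also raised there, by 1.42 times (1.36 to 1.48).

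**Figure D2:**
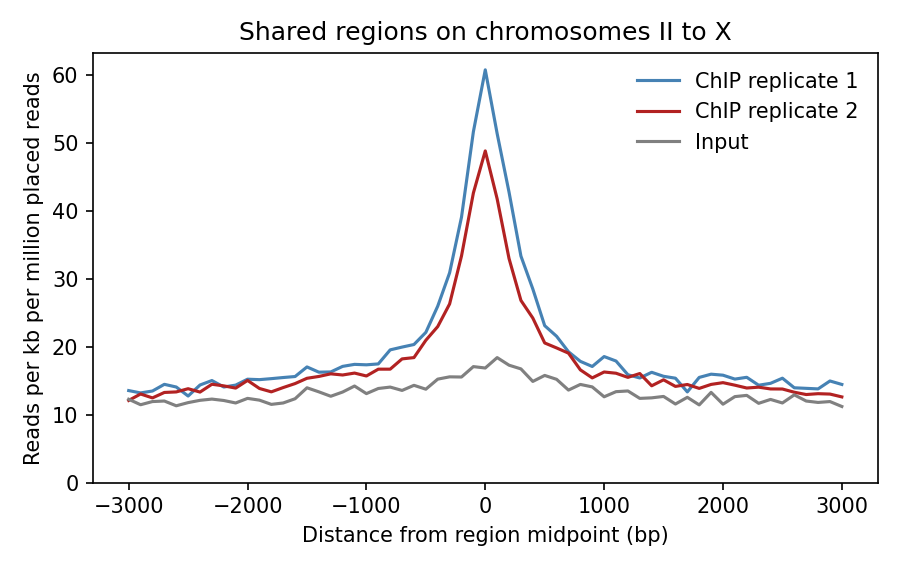
Mean depth in reads per kb, as RPM, against the distance from the midpoint of the 342 shared regions on chromosomes II to X, with 1 line per library. The lines peak at 60.8 in ChIP replicate 1 and 48.9 in ChIP replicate 2 at the midpoint, where the input is at 16.9.

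Of the shared regions, the one with the highest ratios lay on chromosome V from 10715716 to 10716147. It had 44 and 54 reads in the ChIP replicates against 3 in the input, which is 9.27 times the input in replicate 1 (95% interval 2.97 to 46.6) and 7.81 times in replicate 2 (2.54 to 39.1). The next was on chromosome I from 10435706 to 10435996, with ratios of 6.32 (1.965 to 32.35) and 6.08 (1.94 to 30.7). The third, on chromosome III from 11371211 to 11371556, had ratios of 5.90 (1.82 to 30.3) and 6.80 (2.19 to 34.2). A further region on chromosome V, from 12343575 to 12343885, had ratios of 6.53 and 5.79. On chromosome X the region from 9467552 to 9467958 had ratios of 5.69 and 5.79, and that from 2809609 to 2809955 had 6.48 and 5.53. The region on chromosome X from 2729947 to 2730182 had 27 and 35 ChIP reads and 0 in the input. With the input set to 3 reads its ratios were 5.69 and 5.06. The lower 95% limits from the counts were 4.32 and 3.91, with no upper limit. Of the 15 regions named by this rule, 3 lay on chromosome I. All 15 had 4 input reads or fewer, so their ratios are imprecise, and a ranking by ratio favours regions with few input reads. Genes at these positions were not analysed here.

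**Figure D3:**
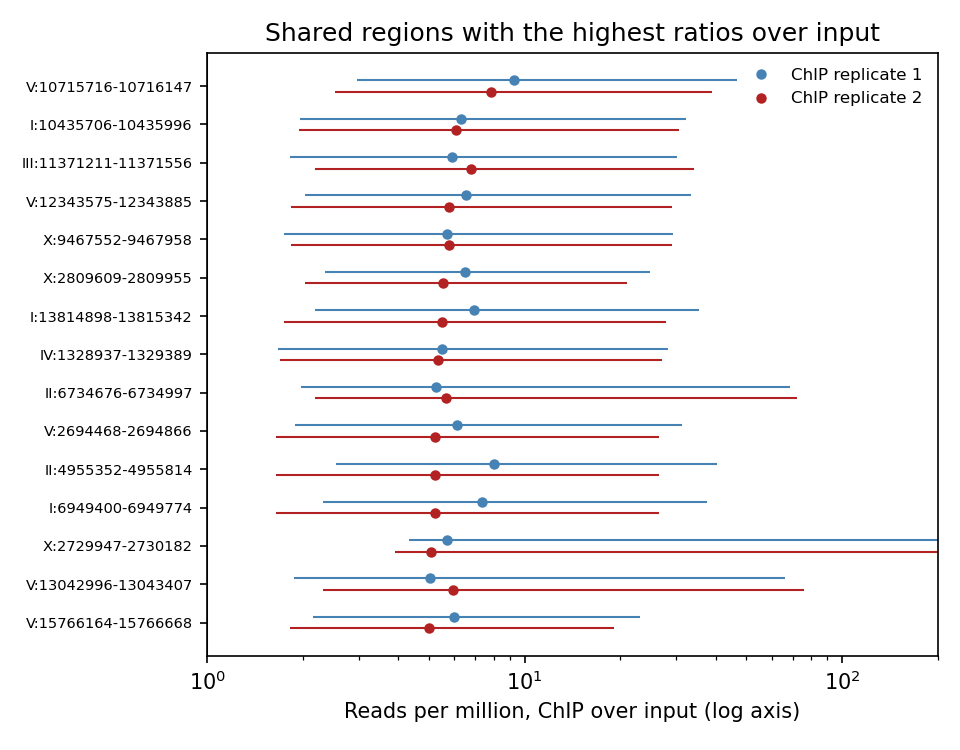
Ratio of RPM, ChIP over input, on a log axis for the 15 shared regions with the highest ratios, with 95% counting intervals as lines and input counts under 3 set to 3 for the points. All intervals lie above 1, and those of the region on chromosome X from 2729947, with 0 input reads, have no upper end and leave the plot.

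Across the genome the replicate-aware test was not able to name windows. In 169337 windows of 500 bp, edgeR's quasi-likelihood test called 0 higher and 0 lower in ChIP at an adjusted p of 0.05. At an unadjusted p under 0.05 it had 5369 higher and 3546 lower, and DESeq2 called 0 as well, with 446 and 52 at an unadjusted p under 0.05. Among so many windows, many pass an unadjusted limit without any effect. Outside all peaks edgeR had 2.37% of windows higher at that limit. With 2 ChIP libraries and 1 input the simulated test found 13% of windows raised 4-fold, so enrichment of the size seen at most peaks was not detectable by this test. Windows in shared regions had a median log2 fold change of 0.92, or 1.09 on chromosomes II to X, against 0.02 outside all peaks, a direction set in advance because the peaks were called from the same reads.

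The third comparison was between the replicates at the regions, of which replicate 1 was the later in L2. With 1 library per stage, a difference between them belongs to these libraries and not to the stage. RPM per region was correlated across the 3111 regions (Pearson r = 0.913, Spearman rho = 0.917), which are not independent replicates. Longer regions hold more reads in both libraries, so the spread of region lengths can by itself raise this correlation. Divided by the length of each region, the correlation was lower, at r = 0.436 and rho = 0.176. Peaks were as short as 1 bp, with 241 and 708 under 100 bp in replicates 1 and 2, which makes such densities noisy. Most regions were also listed for 1 replicate alone, which can lower a correlation per kb. Per kb of the 665 shared regions r and rho were 0.531 and 0.514. Shared regions had a median of 1.24 times the RPM in replicate 1 that they had in replicate 2 (95% interval of the median over regions 1.22 to 1.27). That interval treats regions as independent and does not measure how far another pair of libraries would differ. The counting interval lay above 1 in 127 of them, below 1 in 3 and held 1 in 535. Regions listed for one replicate alone had a median ratio of 1.94 for the 819 of replicate 1 and 0.728 for the 1627 of replicate 2, a direction that their selection from the same reads sets in advance. Most of these did not differ beyond counting error, as the interval held 1 in 484 and 1512 of them.

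Among regions with at least 20 reads in both ChIP libraries together, the one with the largest excess in replicate 1 lay on chromosome III from 5405595 to 5405776, with 18 reads against 3 and a ratio of 8.73 (95% interval 2.55 to 46.3). The region on chromosome II from 4049747 to 4049965 followed, with 20 reads against 4 and a ratio of 7.28 (2.44 to 29.3). At the other end, the region on chromosome V from 4456474 to 4456674 had 2 reads in replicate 1 against 22 in replicate 2 and a ratio of 0.132 (0.0151 to 0.538). The region on chromosome X from 16613853 to 16614140 had 3 against 30 and a ratio of 0.146 (0.0284 to 0.468). These are extremes picked from many regions, and all 10 named this way were listed for 1 replicate only. Regions with fewer reads, left out by this rule, include more extreme ratios.

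The last comparison was of the sequence at region centres with that of the flanks. TAATTA, the core that LIM homeodomain proteins bind, was not more frequent at the centres. It was found in 6.47% of 665 centres and 7.52% of flanks (exact McNemar p = 0.602). The direction depended on the setting, with 18.9% against 16.3% in stretches of 250 bp to each side (exact p = 0.294). The shorter core TAAT[TG] was found in 53.8% of centres and 61.5% of flanks (exact p = 0.0372, adjusted p = 0.132 over 18 patterns). With the read summit as centre it was lower at the centres, at 48.3% against 60.4% (exact McNemar adjusted p = 0.000146). At region midpoints it was also lower over all peaks of replicate 2 (exact McNemar adjusted p = 6.25e-07) and of replicate 1 (adjusted p = 2.78e-05). Around the read summits the shorter core stood at 53.1% against 46.8% in stretches of the same GC content (exact McNemar p = 0.0159), so its direction turned with the control. Its adjusted p of 0.0318 came from a family that also held words picked as higher at these centres. Such words lower the adjusted p of the others, so this is not taken as a call. Centres had a GC content of 42.6% and flanks of 37.6%.

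GAGAGA, the repeat that GAGA-type factors bind, was more frequent at the centres. It was found in 27.9% of centres and 11.7% of flanks (exact McNemar p = 6.43e-13, adjusted p = 1.16e-11), and in 24.7% and 11.7% without chromosome I. Of all 2080 words of 6 bases, 70 were higher and 27 lower at the centres at an adjusted p of 0.05, and without chromosome I 15 were higher and 0 lower. GA-rich, CG-containing and CA-rich words were among those that were higher, the last including CACACA with 18.2% of centres and 6.54% of flanks. AGAGAC was found in 19.8% of centres and 6.92% of flanks, GCACAC in 15.6% and 3.91%, CGTCTC in 19.7% and 7.44%, and CGCGCA in 11.9% and 2.03%. The lower words were rich in A and T, such as AAAATT with 40.6% and 54.7%.

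**Figure D4:**
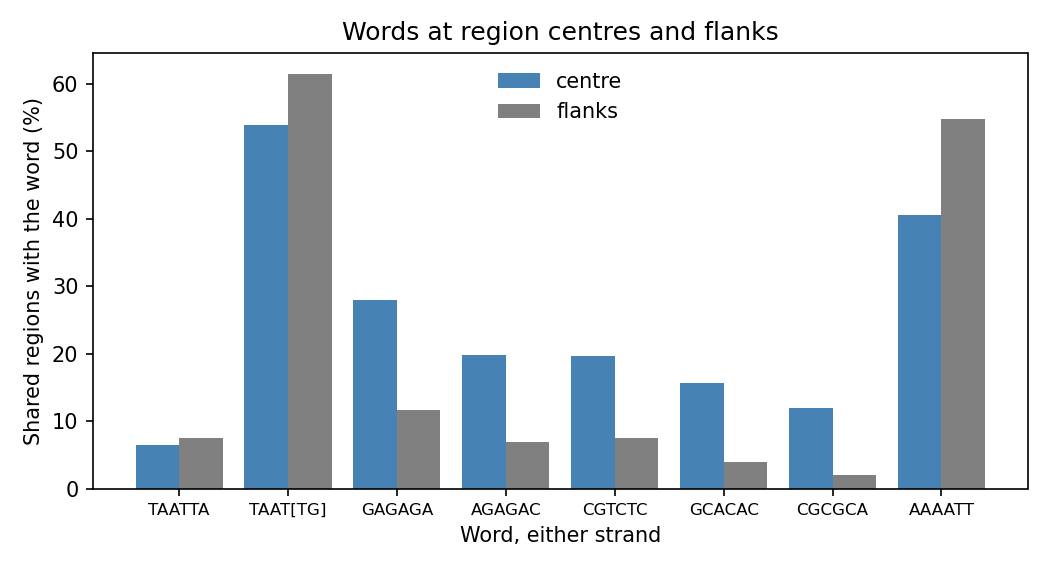
Share of the 665 shared regions that hold each word on either strand within 100 bp of the midpoint (centre) and, as the mean of both sides, in stretches of the same width 500 bp away (flanks). TAATTA is at 6.47% and 7.52%, and GAGAGA at 27.9% and 11.7%.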

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

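All tests in this part were chosen after the data were seen. Reads that matched no place in the genome were searched for a GFP coding sequence, GFP being part of the tag, with exact matches of 20 bases. The sequence searched was a standard one from general knowledge, as the GFP variant in the tag is not given in the sources used here. GFP reads numbered 27 in ChIP replicate 2, 11 in ChIP replicate 1 and 5 in the input. In RPM this is 10.4, 6.18 and 4.45. ChIP replicate 2 stood above the input in a test of counting error (exact one-sided p = 0.0478), but not after adjustment over the 4 comparisons made (adjusted p = 0.191). The counts correspond to 1.59 copies per genome in ChIP replicate 2 (95% interval 1.05 to 2.32), 0.989 in ChIP replicate 1 (0.494 to 1.77) and 0.666 in the input (0.216 to 1.55), at the median depth of each library. These are low estimates, since a sequencing error within the 20 bases, or a difference between the variants, removes a read. Bacterial small-subunit ribosomal RNA gene reads, sought in the same way with a sequence from general knowledge, numbered 320, 170 and 270 in ChIP replicate 1, ChIP replicate 2 and the input. In RPM they were 180, 65.6 and 240.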

How the results depend on the processing

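Of the alternatives, 24 were set before the data were examined. Of 67 in all, 43 left the value on the same side of its threshold, on unadjusted p for words, or within its spread, 20 moved it, 1 brought it past a threshold on the unadjusted p alone and 3 turned its direction. Peak sharing stayed between 42.1% and 52.8% of replicate 1 and above rotated positions under all 4 alternatives, and 0 windows were called under all 5. The median ratio over input was 1.68 and 1.57 in replicates 1 and 2 over all peaks of either list, where 1500 of 3111 regions had under 3 input reads and were held at the floor. In replicate 1 it was 2.98 without chromosome I and 2.18 on it. The correlation was 0.876 with a pseudocount of 0.1, 0.945 in shared peaks, 0.921 with 1 read per position and strand, 0.920 without chromosome I, 0.436 per kb and 0.531 per kb of shared peaks. The ratio of TAATTA at centres over flanks, 0.86, turned to 1.16 with 250 bp, 1.096 without chromosome I and 1.45 against GC-matched stretches, none past the threshold, and the shorter core, at 0.875, passed it before adjustment (exact p = 0.0372) but not after (adjusted p = 0.132); the cause was not tested. Without replicate 1 or 2 this ratio was between 0.872 and 0.888. The GAGAGA ratio was between 1.80 and 2.97 under all 8 alternatives, and between 1.84 and 2.12 without 1 replicate. The strongest 170 shared regions were chosen by the smaller of the replicates' ratios over input and searched around the read summit. There, at 1.95, the GAGAGA call was lost on adjustment (exact McNemar p = 0.0400, adjusted p = 0.316). With the read summit as centre 192 words were higher and 141 lower, without chromosome I 15 and 0, and with both changes 82 and 40. The density of peaks on chromosome I over the others was 4.69 and 3.38. At the stricter of 2 p limits (0.001) and a slope from all bins it was 6.06 and 4.21, and leaving out the bins with extreme input depth, whose effect is weighed with the other observations, gave 1.17 and 0.969, or 2.35 and 1.56 at the looser limit (0.01).

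The alternatives set in advance on promoters, gene lists, RNA genes, the ceh-14 and unc-119 loci and the sharing without those loci were not run, because no annotation in WS180 was at hand. Without either ChIP library the window test has no residual degrees of freedom and was not run. No paired analysis was possible because the ChIP and input groups share only 1 replicate number. Depth limits single regions: a median of 11 input reads stands behind each shared region, and the window test needed more than 4-fold enrichment for most windows.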

Other observations

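All tests in this part were chosen after the results were seen, and no biological explanation given by the design was tested. Other words at the centres included binding sequences of known factors. With the read summit as centre, the GC box, bound by Sp and KLF factors, was found in 8.57% of centres and 3.08% of flanks (exact McNemar p = 0.000535, adjusted p = 0.00241 over 18 patterns). Against GC-matched stretches it was found in 9.47% and 5.86% (exact McNemar p = 0.0127). The adjusted p of 0.0272 there came from the family that also held picked words, so it is not taken as a call. At the region midpoint the call of the GC box against flanks was lost (5.86% and 2.86%, adjusted p = 0.122) but held within 250 bp (adjusted p = 0.000826) and over all peaks of replicate 2 (adjusted p = 0.000453) and of replicate 1 (adjusted p = 0.00461). In the strongest 170 regions, where fewer regions were tested, it was found in 7.35% of centres and 2.06% of flanks (adjusted p = 0.516). The worm splice acceptor TTTTCAG was found in 8.80% of centres and 19.5% of flanks (adjusted p = 9.53e-06), with no call at the midpoint of shared regions (adjusted p = 0.0760) nor over all peaks of replicate 1 (adjusted p = 0.264), but one over all peaks of replicate 2 (adjusted p = 0.00140), and in 9.62% against 9.92% of GC-matched stretches (adjusted p = 1). At the summit the TATA box (adjusted p = 0.0232) and the heat shock element (adjusted p = 0.0378) were lower at the centres. GATA was not called there, but was lower within 250 bp of the midpoint (8.95% and 13.8%, adjusted p = 0.0360) and over all peaks of replicate 1 (adjusted p = 0.0166), with no call over all peaks of replicate 2 (adjusted p = 0.0996). The E2F pattern was higher within 250 bp alone (10.1% and 5.19%, exact McNemar adjusted p = 0.0103). The CRE pattern was higher over all peaks of replicate 2 alone (7.13% and 4.93%, adjusted p = 0.0151). Neither was called against GC-matched stretches (adjusted p = 0.101 and 0.334). Against GC-matched stretches the TATA box, the heat shock element and GATA had no call (adjusted p = 1, 0.101 and 0.231).

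The first pattern was the excess of peaks on chromosome I. More ChIP reads from that chromosome do not account for it, since its share of reads in ChIP replicate 1 was 1.04 times that in the input, nor does a larger number of sites account for the whole excess, since with 1 scale for the genome windows above input in both replicates, at a binomial limit of 0.001, were 1.27 times as frequent there as elsewhere (95% interval 1.02 to 1.57). A candidate explanation is that the input was scaled too low on chromosome I. The q-values imply an input factor of 0.921 on I against 1.92 elsewhere in replicate 1 and of 1.24 against 2.39 in replicate 2, and slopes of ChIP on input counts in 10000-bp bins were likewise low on I, at 0.611 and 1.21, but rose to 1.99 and 2.51 without 2 bins, of which that from 15060001 to 15070000, near the end that carries the ribosomal DNA repeats, had 6352 input reads against a median of 113. A recount of the listed peaks at a binomial p limit of 0.001 used slopes with and without those bins. Without them, peaks in replicates 1 and 2 were 1.17 and 0.969 times as dense on I as elsewhere. With them the ratios were 6.06 and 4.21, and in the full lists 4.69 and 3.38. Without the bins, 19.3% and 20.6% of the peaks on I were kept, against 77.4% and 72.0% elsewhere. The recount only drops listed peaks, and no other chromosome had such bins. A lower density on I was therefore set in advance, and only the size of the fall is informative. In replicate 1 the slope of 0.611 lay below the implied factor of 0.921, which can raise the ratio of 6.06. At a limit of 0.01, without the bins, densities on I were 2.35 and 1.56 times those elsewhere. Part of the excess, more sites among its explanations, therefore stays open.

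The second pattern was the frequency of GAGA, CA-rich and CG-containing words at the centres without an excess of TAATTA. Base composition as the whole cause of the GAGAGA excess is argued against by its ratio of 1.87 over GC-matched stretches (adjusted p = 2.66e-09). Whether composition hides an excess of TAATTA stays open, as its ratio of 1.45 over such stretches did not pass the test (exact p = 0.130). Weak peaks that dilute it stay open as well, since the strongest 170 shared regions had TAATTA in 6.76% of centres, the mean of 11 and 12 regions under the masks of both flanks (95% limits of the pair 3.27 and 12.01%), and in as many flanks, which leaves room for a frequency of 10.1%, the level set for an excess. These regions were ranked by ratio over input, which favours regions with few input reads. The input was itself raised 1.61 times at the centres of all shared regions and 1.42 times on chromosomes II to X, and binding through other proteins was not tested.

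The third pattern was a stretch of chromosome X from 7517501 to 7552500, 35 kb long, with raised depth in all 3 libraries. It was the longest of 4 stretches of at least 8 bins of 2.5 kb that were all at 1.5 times the genome median or more in all libraries, and stood at 3.30 and 3.33 times the median in ChIP replicates 1 and 2 and 3.08 times in the input (95% interval 2.91 to 3.27). The stretch was chosen for raised depth in the input as well, so a raised input could not test immunoprecipitation along it. On the other 3 stretches, chosen alike, the input stood at 1.94 to 2.14 times the median. PCR copies do not account for the input's rise on the longest stretch, as it stood at 3.02 times with 1 read per position and strand. Such copies were only 1.90% of placed input reads, so this check had little room to fail. Extra copies of that DNA in the strain, such as a large genomic construct, may account for the rise. The rise in ChIP replicates 1 and 2 was 1.07 and 1.08 times that in the input. On the other 3 stretches it was 1.38 to 1.51 and, with a smaller contrast, 1.17 to 1.23 times. Depth was uneven along the longest stretch, with input bins from 1.63 to 5.59 times the median. GFP reads in the input came to 0.666 copies per genome (95% interval 0.216 to 1.55), a low estimate. That is fewer copies than the rise would need if each extra copy carried the tag. The tagged gene, ceh-14, is on chromosome X, but whether the stretch holds it was not analysed here.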
